A study of Mus musculus with 18 samples.

How the data were processed

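RNA was sequenced from 3 mouse cancer cell lines grown in culture: 4T1 (mammary carcinoma), MC38 (colon adenocarcinoma) and LLC (Lewis lung carcinoma). Each line had 3 libraries from cells given the solvent DMSO (control) and 3 from cells given 100 µM sildenafil citrate, an inhibitor of the phosphodiesterase PDE5, for 24 hours in 4T1 and MC38 and 48 hours in LLC. The 18 libraries form 6 groups, taken from the labels. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Per the labels, libraries were made with a stranded polyA mRNA kit and sequenced from both ends for 100 cycles per read. MC38 and LLC libraries nevertheless held much RNA without a poly(A) tail, as described below.

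The authors deposited a table of expected counts per gene. Per the submitters' processing notes, bcl2fastq 2.17, cutadapt 1.18, STAR 2.7.0f and RSEM 1.3.1 were used with genome build mm10. The order of these tools, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes may not have been told apart. RSEM divides reads shared by near-identical genes between them, and the counts of histone genes and other close paralogs are uncertain for that reason. Between 4.30% and 6.91% of the values in a library were not whole numbers. All 55450 gene identifiers and symbols matched GENCODE release M21 for GRCm38 (mm10), from which gene positions, types and exon lengths were taken. A symbol was shared with another identifier in 217 cases.

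Expected counts were rounded to whole numbers. Library totals ran from 26348654 to 61600646 counts, and 18041 to 19633 genes had a count. Genes were tested within each line on its 6 libraries with edgeR 4.0.16 in R 4.3.3 (TMM factors, the default expression filter, robust quasi-likelihood F test, 4 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 fold change is sildenafil over control, and its standard error (SE) is its size divided by the square root of F. CPM values were scaled by TMM within the line unless stated. Differences between lines were tested on all 18 libraries with 1 coefficient per group. Overlaps between lines were set beside the number given by independent lists, since the lines have separate controls. Such a number leaves out any factor common to the libraries of different lines.

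Before the data were examined, 33 gene lists were fixed, 4 of them markers of other cell types, together with the design, the alternatives and the rule for naming genes. Lists with at least 3 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over lists), and again with an estimated correlation and with fry. The rule named, per line, the 8 genes with the largest rise and the 8 with the largest fall (adjusted p under 0.05, mean of at least 5 CPM, no overlap between groups, no predicted gene name), 12 sterol and PDE5 genes whatever their values, and up to 4 members with the smallest adjusted p of each called list. Across lines it named the 8 genes per direction with the largest smallest change, and 4 per direction and pair of lines with the largest difference. Not every named gene is given in the text, and the results of some are not reported here.

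Counts were simulated with 200 genes drawn to change per line, and with the cholesterol synthesis enzymes raised 1.5-fold besides. Of the drawn genes that passed the filter, the 4T1 test (13763 genes) recovered 65.2% of changes of 1.3-fold, 84.8% of 1.5-fold and 87.1% of 2-fold. For MC38 (13237 genes) the shares were 60.6%, 68.2% and 87.7%, and for LLC (13387 genes) 60.6%, 70.1% and 89.2%. Wrong calls made up 9.42%, 7.51% and 6.78% of the calls in these simulations, above the nominal rate of 0.05. Far fewer genes were changed here than were called in the data, so recovery and wrong calls may differ there. The test of differences between MC38 and 4T1 (15109 genes) recovered 45.9%, 67.2% and 80.3%, with 3.12% wrong calls. In each line's simulation camera called 1 list, the list that had been changed. The drawn genes were taken from outside the fixed lists, and counts varied independently between genes. This result therefore does not measure how often camera calls a list wrongly in these data.

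Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals alone, no filter and a stricter filter (5 CPM in 3 libraries), unrounded counts, the replicate number as a block, each library left out, all 18 libraries in 1 fit, a 2-fold threshold and only the libraries of the compared lines. Protein-coding genes alone, and the level of Gm26917 as a covariate, were added after seeing the data. Transcript GC content was computed with Biostrings 2.70.1. Plots were drawn with matplotlib 3.10.9.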

Results

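Gene expression was measured by RNA sequencing in 4T1, MC38 and LLC cells given DMSO or 100 µM sildenafil citrate, with 3 libraries in each of the 6 groups. Total counts per library ran from 41070021 to 61600646 in 4T1, 29438187 to 36417399 in MC38 and 26348654 to 32129771 in LLC. The title of the series names PDE5, NPC1 and cholesterol trafficking, and each line's comparison asks which genes sildenafil changed. Values below are log2 fold changes ± SE with n = 3 libraries per group unless stated. The lists described within each line were called by camera with the preset correlation. A list whose adjusted p with an estimated correlation is 0.05 or more lost that call. Such a loss alone does not show that the members moved together. MHC class I genes in LLC lost their call at an estimated correlation of -0.0426 (camera adjusted p = 0.0594). In 4T1 the camera adjusted p of the cholesterol synthesis enzymes went from 8.38e-91 to 0.000707 at an estimated correlation of -0.0309. In these cases the setting raised the adjusted p without a positive estimated correlation between members.

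In 4T1 cells treated for 24 hours, genes of cholesterol synthesis and interferon-response genes rose, and genes of ribosome biogenesis fell. The list call of the cholesterol genes held with an estimated correlation, while those of the interferon-response genes (adjusted p = 0.0974) and the ribosome biogenesis genes (adjusted p = 0.0668) were lost with it. All 20 cholesterol synthesis enzymes rose (20 adjusted over the list alone), with a median log2 fold change of 1.99 (camera adjusted p = 0.000707 with an estimated correlation). Hmgcs1, an enzyme of the mevalonate pathway on chromosome 13 (119690379 to 119708260), went from 47.9 ± 1.70 to 316 ± 9.74 CPM (mean ± SD), a log2 fold change of 2.72 ± 0.0365. Insig1, which retains SREBP proteins in the endoplasmic reticulum, rose by 3.29 ± 0.0317, and the isomerase Idi1 by 2.92 ± 0.0391. Srebf2, the transcription factor of these genes, rose by 0.97 ± 0.0269.

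Npc1, the lysosomal cholesterol transporter gene on chromosome 18 (12189692 to 12236400), rose by 0.39 ± 0.0632 in 4T1 (adjusted p = 0.000124). Npc2, its partner in the lysosome, rose by 1.17 ± 0.0301 (adjusted p = 3.53e-12). Pde5a was near the limit of detection at 0.442 ± 0.0985 CPM in control and 0.845 ± 0.0381 CPM in sildenafil libraries. It rose by 0.95 ± 0.239 (adjusted p = 0.00308). Abcg1, a sterol exporter gene, fell by 1.55 ± 0.179 from 2.80 CPM. In the list of endolysosomal cholesterol trafficking 13 of 18 measured genes rose and 3 fell (the same adjusted over the list alone), and this call was lost with an estimated correlation (adjusted p = 0.127). Of the lysosomal hydrolases and proton pump genes, 22 of 24 rose and 1 fell (23 and 1 adjusted over the list alone), among them Neu1 by 1.40 ± 0.0472 and Gla by 1.41 ± 0.0518 (camera adjusted p = 0.0552 with an estimated correlation).

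All 36 interferon-response genes rose in 4T1 (36 adjusted over the list alone), with a median of 2.43, and the camera call was lost with an estimated correlation (adjusted p = 0.0974). Ifit3, an antiviral effector gene, rose by 4.08 ± 0.111, from 3.82 ± 0.294 to 64.9 ± 7.96 CPM. Oas2 rose by 3.83 ± 0.289, Mx2 by 3.42 ± 0.136 and Ifit1 by 2.90 ± 0.0539. All 14 MHC class I genes rose (14 adjusted over the list alone; camera adjusted p = 0.0373 with an estimated correlation), among them the immunoproteasome gene Psmb8 by 1.09 ± 0.0452 and Tapbp by 1.34 ± 0.0266. Beside these genes, Cd74, a leukocyte marker also induced by interferon, rose from 26.7 ± 0.621 to 48.2 ± 3.68 CPM, and the macrophage marker Cd68 rose from 10.2 ± 0.273 to 38.7 ± 0.767 CPM, by 1.93 ± 0.0471. These were the leukocyte markers expressed highly enough to be tested. The median leukocyte marker stood at 0.00785 CPM in control and 0.00761 CPM in sildenafil libraries (TMM over 18 libraries). Of 3 measured fibroblast markers 2 rose and 1 was not called, and camera did not call the list (adjusted p = 0.0558). Pdgfra averaged 27.95 CPM in control and 54.63 CPM in sildenafil libraries (TMM over 18 libraries).

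All 27 genes of the MYC and ribosome biogenesis list fell in 4T1 (27 adjusted over the list alone), with Myc falling by 1.22 ± 0.0279 and Nop2 by 1.12 ± 0.0305 (camera adjusted p = 0.0668 with an estimated correlation). Of the S-phase genes 35 of 38 fell (35 adjusted over the list alone), Cdc6 by 0.82 ± 0.0508 (camera adjusted p = 0.363 with an estimated correlation). In the fatty acid synthesis list 13 of 14 rose and 1 fell (the same adjusted over the list alone), Elovl6 by 1.77 ± 0.0382 and Scd1 by 1.57 ± 0.0338 (camera adjusted p = 0.0373 with an estimated correlation). The YAP and SRF target Amotl2 fell by 1.04 ± 0.0284, as did 15 of the 21 measured genes of its list, while 3 rose (the same adjusted over the list alone; camera adjusted p = 0.281 with an estimated correlation). Bmf, a pro-apoptotic BH3-only gene, rose by 2.33 ± 0.0953. Of the integrated stress response genes 19 of 31 fell and 6 rose (the same adjusted over the list alone; camera adjusted p = 0.548 with an estimated correlation), with the amino acid transporter gene Slc7a5 falling by 0.74 ± 0.0343 and Ddit4 rising by 0.97 ± 0.0287. Of the glycolysis and hypoxia genes 23 of 30 rose and 3 fell (24 and 3 adjusted over the list alone; camera adjusted p = 0.309 with an estimated correlation). Sterol regulation and uptake genes rose in 7 of 10 cases and fell in 2 (the same adjusted over the list alone; camera adjusted p = 0.0115 with an estimated correlation), among them Lpin1 by 2.58 ± 0.0564. Autophagy genes rose in 14 of 18 cases (camera adjusted p = 0.309 with an estimated correlation), and sphingolipid genes in 13 of 17 with 4 that fell (0.127). NRF2 genes rose in 12 of 18 cases and fell in 4 (adjusted p = 0.0974 with an estimated correlation), NF-kB and inflammatory genes rose in 13 of 25 and fell in 5 (0.127), and apoptosis regulators rose in 11 of 16 and fell in 2 (0.143). Mitosis genes fell in 19 of 30 cases and rose in 2 (adjusted p = 0.666 with an estimated correlation). In these lists the counts adjusted over the list alone were the same.

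In total 9285 of 13914 genes tested changed, 4658 up and 4627 down, and 1033 of them by at least 2-fold (834 up, 199 down).

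In MC38 cells treated for 24 hours, genes of cholesterol synthesis, glycolysis and lysosomes rose, and genes of ribosome biogenesis fell. Of the 20 cholesterol synthesis enzymes 18 rose (18 adjusted over the list alone), with a median of 1.67 (camera adjusted p = 0.00016 with an estimated correlation). Hmgcs1 rose by 2.75 ± 0.0367, Insig1 by 2.31 ± 0.0288 and Nsdhl by 2.30 ± 0.0514. Tm7sf2 stood at -0.13 ± 0.161 (adjusted p = 0.574). Npc1 rose by 0.40 ± 0.0378 (56.9 ± 1.15 to 75.0 ± 2.76 CPM), Npc2 by 0.66 ± 0.0314, Srebf2 by 0.72 ± 0.0404 and Pde5a by 0.31 ± 0.0602 (12.6 ± 0.281 to 15.6 ± 0.502 CPM). Srebf1 stood at 0.0011 ± 0.0366 (adjusted p = 0.986). Abca1, the sterol exporter, fell by 1.67 ± 0.06 from 63.3 ± 4.83 to 19.9 ± 1.12 CPM.

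Among the other MC38 lists, 28 of 30 glycolysis and hypoxia genes rose and 1 fell (the same adjusted over the list alone), among them Bnip3 by 1.33 ± 0.0571 and Pdk1 by 0.78 ± 0.033 (camera adjusted p = 0.0465 with an estimated correlation). Of 28 measured genes of the integrated stress response 18 rose and 4 fell (19 and 4 adjusted over the list alone), with Ddit3 up by 1.40 ± 0.0664, Trib3 by 1.12 ± 0.047 and Atf4 by 0.63 ± 0.0286 (camera adjusted p = 0.121 with an estimated correlation). Lysosomal genes rose in 23 of 24 cases (23 adjusted over the list alone), led by Gpnmb at 1.40 ± 0.0404 (camera adjusted p = 0.0451 with an estimated correlation). Ribosome biogenesis genes fell in 26 of 27 cases (26 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.0131 with an estimated correlation). Interferon-response genes rose in 27 of 34 measured cases (28 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.0547 with an estimated correlation). Beside them, the leukocyte markers Csf1r and Cd68 rose, Csf1r from 2.69 ± 0.147 to 4.52 ± 0.514 CPM and Cd68 from 2.80 ± 0.374 to 4.45 ± 0.102 CPM, while Lyz2 stood at 0.53 ± 0.301 (adjusted p = 0.183).

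Sterol regulation and uptake genes rose in 7 of 10 cases and fell in 1 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00117 with an estimated correlation). Fatty acid synthesis genes rose in 12 of 14 (12 adjusted over the list alone; adjusted p = 0.0016 with an estimated correlation), Elovl6 by 1.60 ± 0.0286. Endolysosomal cholesterol trafficking genes rose in 12 of 18 cases (12 adjusted over the list alone; camera adjusted p = 0.0451 with an estimated correlation), and autophagy genes in 11 of 17 (14 adjusted over the list alone; 0.0295). Sphingolipid genes rose in 12 of 17 cases (12 adjusted over the list alone; adjusted p = 0.0397 with an estimated correlation), among them Ugcg by 0.81 ± 0.035. Camera calls that were lost with an estimated correlation were those of the unfolded protein response (14 of 19 rose, adjusted p = 0.15), MHC class I genes (11 of 14 rose and 1 fell, 0.274) and TGF-beta targets (3 of 9 rose and 1 fell, 0.15). The same held for YAP and SRF targets (15 of 20 fell and 1 rose, 0.176), heat shock genes (9 of 14 fell and 1 rose, 0.176), mitosis genes (15 of 30 fell, 0.121) and oxidative phosphorylation genes (16 of 28 fell and 2 rose, 0.508). Adjusted over the list alone, 17 YAP and SRF targets fell and 1 rose, 16 mitosis genes fell and 1 rose, and 18 oxidative phosphorylation genes fell and 2 rose. For the unfolded protein response, MHC class I, TGF-beta and heat shock lists the counts adjusted over the list alone were the same.

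In total 5047 of 13363 genes changed in MC38, 2602 up and 2445 down, 129 of them by at least 2-fold (98 up, 31 down). Polr2a, which encodes the large subunit of RNA polymerase II, fell by 1.31 ± 0.34 (adjusted p = 0.0458), and Palld, an actin-associated gene, by 1.01 ± 0.19. Gm26917, a predicted gene chosen after its values were seen, fell from 11190 ± 2643 to 5414 ± 552 CPM. Palld and Srebf2 were among the genes that moved with it between libraries of the same group in both MC38 and LLC, and Polr2a was not. With the level of Gm26917 as a covariate, added after seeing the data, 937 genes changed. Polr2a then stood at -0.0915 (adjusted p = 0.957), Palld at -0.21 (adjusted p = 0.648) and Pde5a at 0.32 (adjusted p = 0.291). That covariate shared 0.856 of its variance with treatment in MC38, which alone widens the errors. With the covariate the cholesterol list had a median of 1.72. Leaving out any 1 MC38 library ended the call of Polr2a (adjusted p from 0.0557 without sildenafil replicate 3 to 0.14 without sildenafil replicate 2), as did the fit with no filter on low counts (adjusted p = 0.0778). The call of Palld was lost without sildenafil replicate 1 (0.0616) or 2 (0.0663). In 4T1 Polr2a averaged 187.6 CPM in control and 127.6 CPM in sildenafil libraries without overlap (TMM over 18 libraries). Gm26917 rose there, from 158.6 to 254.9 CPM. In LLC Polr2a averaged 115.1 and 52.66 CPM with overlap, and Gm26917 averaged 19640 and 8824 CPM.

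In LLC cells treated for 48 hours all 20 cholesterol synthesis enzymes rose (20 adjusted over the list alone), with a median of 0.80, and the call was lost with an estimated correlation (camera adjusted p = 0.0621). Idi1 rose by 1.21 ± 0.0633, Hmgcs1 by 1.13 ± 0.0656 and Insig1 by 1.01 ± 0.052. Npc2 rose by 0.51 ± 0.0495 and Npc1 by 0.22 ± 0.0661 (adjusted p = 0.035). The Npc1 call was lost with DESeq2 (adjusted p = 0.0509) and without control replicate 2 (adjusted p = 0.0818), sildenafil replicate 1 (adjusted p = 0.116) or sildenafil replicate 3 (adjusted p = 0.099). Srebf2 stood at 0.02 ± 0.125 (adjusted p = 0.929), and at 0.30 (adjusted p = 0.00362) with the level of Gm26917 as a covariate, added after seeing the data. Srebf2 was among the genes that moved with Gm26917 between libraries of the same group in both MC38 and LLC. Pde5a stood at 0.04 ± 0.111 (adjusted p = 0.802). Abca1 rose from 5.55 ± 0.0824 to 12.5 ± 0.726 CPM (adjusted p = 1.92e-05).

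Interferon-response genes rose in 12 of 22 measured cases in LLC (13 adjusted over the list alone; camera adjusted p = 0.0604 with an estimated correlation). Beside them, the leukocyte marker Lyz2 rose from 1.49 ± 0.053 to 3.35 ± 0.387 CPM, while Cd68 stood at 0.17 ± 0.221 (adjusted p = 0.605). MHC class I genes rose in 7 of 13 cases (7 adjusted over the list alone; adjusted p = 0.0594 with an estimated correlation), Tapbp by 0.84 ± 0.0558. Integrated stress response genes fell in 21 of 29 cases in LLC and 2 rose (23 and 3 adjusted over the list alone), among them the cystine transporter gene Slc7a11 by 0.86 ± 0.0543 (camera adjusted p = 0.121 with an estimated correlation). Of the glycolysis and hypoxia genes 15 of 31 fell and 0 rose (the same adjusted over the list alone), Ero1l by 0.98 ± 0.0556 (camera adjusted p = 0.188 with an estimated correlation). S-phase genes rose in 19 of 38 cases and 1 fell (24 and 1 adjusted over the list alone), Cdc6 by 0.40 ± 0.0518 (camera adjusted p = 0.337 with an estimated correlation). Further camera calls, each lost with an estimated correlation, were those of sterol regulation and uptake (6 of 11 rose and 1 fell, adjusted p = 0.0684), LXR targets (6 of 7 rose, 0.0684), endolysosomal cholesterol trafficking (8 of 17 rose and 1 fell, 0.079) and fatty acid synthesis (11 of 14 rose and 1 fell, 0.0647). So were those of CREB targets (7 of 13 rose and 2 fell, adjusted p = 0.079), lysosomal genes (15 of 24 rose, 0.079), sphingolipid genes (9 of 17 rose and 2 fell, 0.0719) and NF-kB and inflammatory genes (6 of 16 rose, 0.0862). The last were mesenchymal and matrix genes (6 of 21 rose and 3 fell, 0.187) and TGF-beta targets (4 of 9 rose and 1 fell, 0.121). Adjusted over the list alone, 3 sterol regulation genes fell, 8 CREB targets, 17 lysosomal genes and 7 NF-kB genes rose, 10 sphingolipid genes rose and 3 fell, and 7 mesenchymal genes rose and 4 fell. The remaining counts in these lists were the same adjusted over the list alone.

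The matrix gene Tgfbi rose by 1.81 ± 0.0673, the fatty acid oxidation gene Cpt1a by 1.45 ± 0.0519 and the phosphodiesterase gene Pde4b by 1.37 ± 0.0759. Beside the matrix genes, all 4 measured fibroblast markers rose (4 adjusted over the list alone), Pdgfra by 1.07 ± 0.0544 and Col6a1 by 0.88 ± 0.0532 (camera adjusted p = 0.0594 with an estimated correlation). The median of these markers was 0.86 in LLC and 0.95 in 4T1, where 2 of 3 rose. In MC38 2 of 5 rose and 2 fell. Tenm4 fell by 1.88 ± 0.0964 and Neat1 by 1.28 ± 0.117.

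In LLC 3702 of 13561 genes changed, 2046 up and 1656 down, 273 by at least 2-fold (105 up, 168 down). Control replicate 3 lay nearest to the sildenafil libraries on the first principal component, at -8.54 beside -27.2 and -27.3 for the other controls. Without it 5994 genes changed, and without control replicate 1, sildenafil replicate 2 or sildenafil replicate 3 the counts were 2299, 1999 and 1841. Without control replicate 2 the genes that fell numbered 997. With the level of Gm26917 as a covariate, added after seeing the data, 2251 genes changed.

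**Figure D1:**
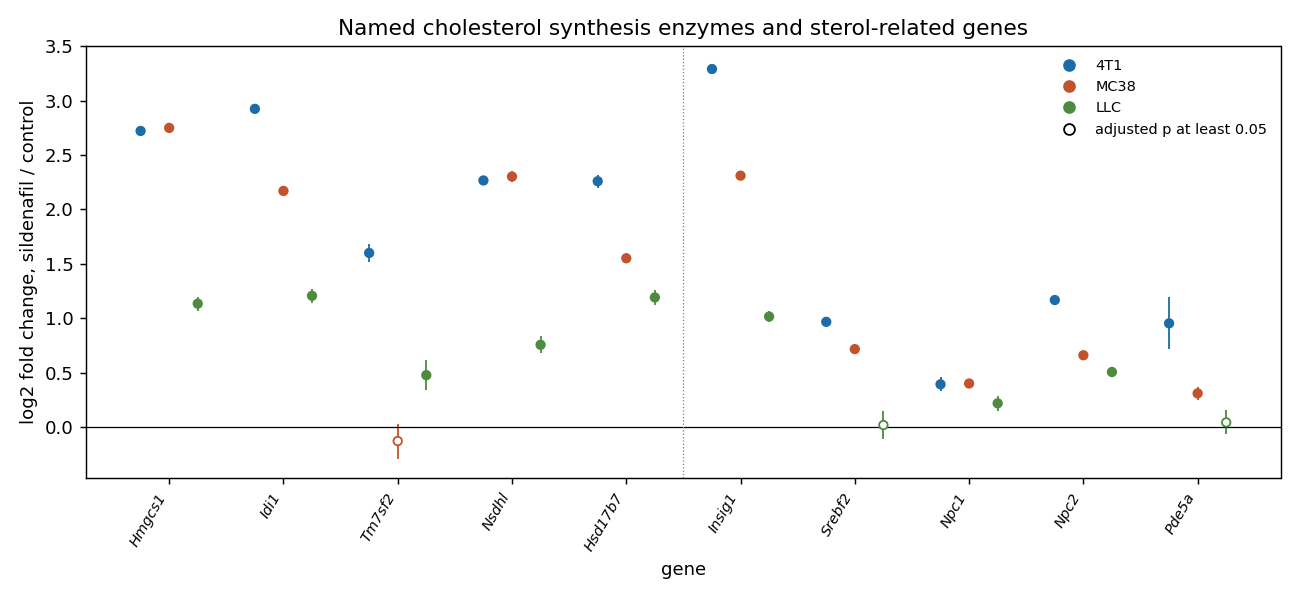
Log2 fold change of sildenafil over control (vertical axis) for 5 cholesterol synthesis enzymes named in the text and, right of the dotted line, 4 sterol-related genes and Pde5a, in 4T1, MC38 and LLC. Points are edgeR estimates from 3 libraries per group, bars are ± SE and open points did not pass the test. Hmgcs1 lies at 1.13 in LLC, beside 2.72 in 4T1 and 2.75 in MC38.

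The lines were compared to ask which changes they share. Among the 11274 genes tested in all 3 lines, 593 rose and 303 fell in each, where independent lists would give 133.3 and 103.3. Of the cholesterol synthesis enzymes 18 were among them. With library totals alone as the scaling 717 rose and 206 fell in each. The overlap was not repeated with the level of Gm26917 as a covariate, so a factor common to MC38 and LLC libraries may add to it. Among the shared rises were Hmgcs1 (2.72 in 4T1, 2.75 in MC38, 1.13 in LLC), Hsd17b7 (2.26, 1.55 and 1.19) and Idh1 (2.30, 1.28 and 1.13). Shared falls included Prodh (-1.21, -0.60 and -0.49) and Ddah1 (-0.76, -0.44 and -0.89). With the level of Gm26917 as a covariate, added after seeing the data, both lost their call in MC38, Prodh at -0.70 (adjusted p = 0.0675) and Ddah1 at -0.46 (adjusted p = 0.103). Genes called in both members of a pair had the same direction in 85.4% of 3789 cases for 4T1 and MC38, 68.1% of 2501 for 4T1 and LLC and 73.3% of 1590 for MC38 and LLC. The shared total of 896 was 539 without LLC sildenafil replicate 2 and 544 without LLC sildenafil replicate 3, with 421 and 409 rises and 118 and 135 falls. The shared falls numbered 186 without LLC control replicate 1, 187 without LLC control replicate 2 and 501 without LLC control replicate 3.

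Responses were then compared between lines directly, where LLC differs from the others in both line and time. Of 16040 genes, 5550 responded differently in MC38 and 4T1, 6739 in LLC and 4T1 and 3576 in LLC and MC38. Cholesterol synthesis enzymes responded less in LLC than in 4T1 (19 of 20 lower and 1 higher, median difference -1.11, camera adjusted p = 0.0127 with an estimated correlation) and than in MC38 (16 lower and 2 higher, median difference -0.86, adjusted p = 0.00507 with an estimated correlation). Interferon-response genes responded less in MC38 than in 4T1 (35 of 36 lower, median difference -1.85, adjusted p = 0.0121 with an estimated correlation). The glycolysis and hypoxia list had a median of 0.39 in MC38 and -0.17 in LLC, and its responses were lower in LLC (27 of 31 lower and 1 higher, or 28 and 1 adjusted over the list alone, median difference -0.55, adjusted p = 0.00507 with an estimated correlation). The integrated stress response list likewise had a median of 0.32 in MC38 and -0.31 in LLC, with lower responses in LLC (22 of 32 lower, median difference -0.43, adjusted p = 0.0249 with an estimated correlation). For the cholesterol, interferon and integrated stress response lists the counts adjusted over the list alone were the same. Camera did not call the list of cGMP signalling genes and phosphodiesterases in 4T1 (7 of 12 rose and 3 fell, adjusted p = 0.512), MC38 (4 of 11 rose and 2 fell, adjusted p = 0.629) or LLC (0 of 15 rose and 2 fell, adjusted p = 0.362), with the same counts adjusted over the list alone. Its median was 0.46 in 4T1 and its mean 0.44, in MC38 these were -0.02 and 0.03, and in LLC 0.0064 and -0.072. With fry, which does not set a list against the other genes, its adjusted p was 0.000581 in 4T1, 0.0273 in MC38 and 0.218 in LLC. Abca1, which fell in MC38 and rose in LLC, differed by 2.86 ± 0.119. Lpin1, up by 2.58 in 4T1, differed by -2.79 ± 0.0855 between LLC and 4T1.

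**Figure D2:**
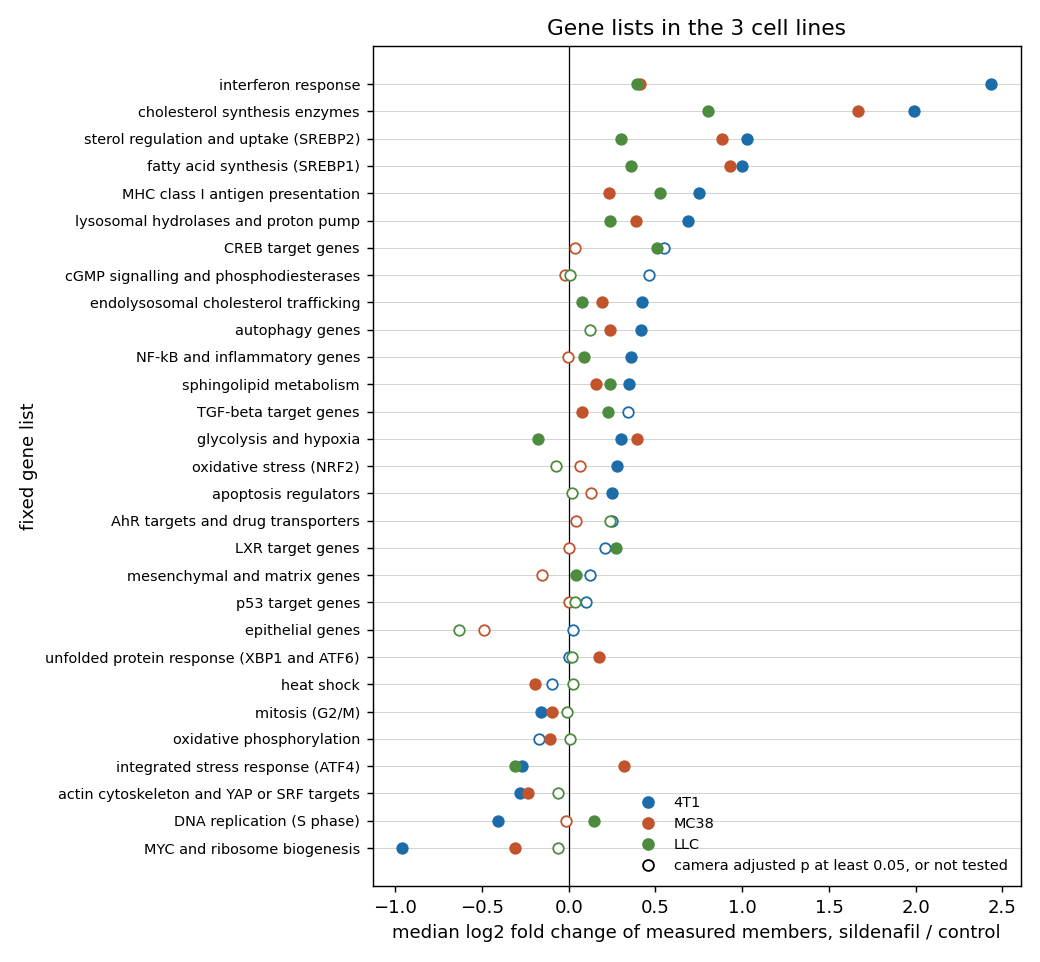
Median log2 fold change of sildenafil over control (horizontal axis) for the measured members of 29 fixed gene lists (vertical axis) in 4T1, MC38 and LLC. Filled points were called by camera with the preset correlation. Interferon-response genes lie at 2.43 in 4T1 and 0.41 in MC38, and cholesterol synthesis enzymes lie above 0 in each line.

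The libraries of the 3 lines also differed in their RNA makeup, and line cannot be separated from library preparation here. Protein-coding genes took 97.1% to 97.3% of the counts in 4T1 libraries and 87.3% to 89.7% in MC38 and LLC libraries. Histone genes took 0.004% to 0.005% in 4T1 and 0.593% to 1.21% in the others. They took 0.785% to 0.853% of the counts in MC38 control libraries and 0.593% to 0.7% in MC38 sildenafil libraries. Rn7sk, a small nuclear RNA without a poly(A) tail, averaged 3.47 ± 0.867 CPM in 4T1 control and 21400 ± 1332 CPM in MC38 control libraries.

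**Figure D3:**
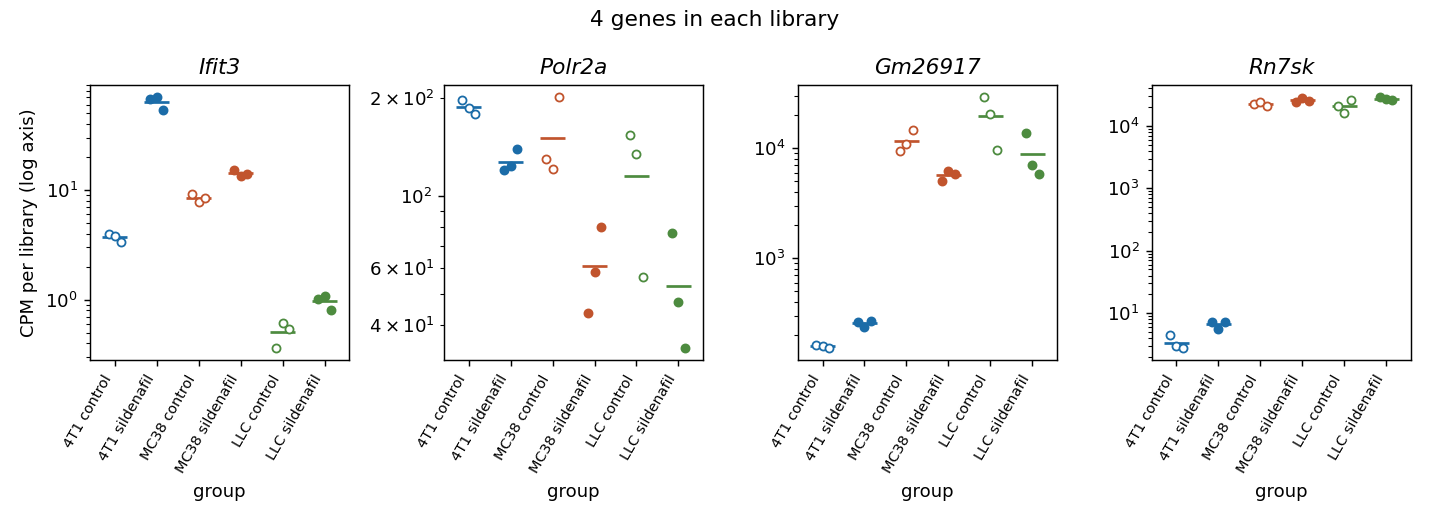
CPM (vertical log axis, TMM over 18 libraries) of Ifit3, Polr2a, Gm26917 and Rn7sk in each library, by group (horizontal axis), with open points for control, filled points for sildenafil and a line at the mean of 3 libraries. Ifit3 averages 3.72 CPM in 4T1 control and 63.8 CPM in 4T1 sildenafil libraries, and Rn7sk lies far lower in 4T1 than in MC38 and LLC.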

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

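The tests of RNA preparation in 4T1 against the other lines and of the sources of the interferon response were chosen after the results were seen. So were those of the overlap and gene length of genes that move with Gm26917. The differences between lines listed here were picked out because sildenafil's effect differed between cell lines by a test of the difference itself, and LLC differs in both line and time. The second and the third pattern weighed were noticed in the libraries and are not such differences.

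The response of 5550 genes differed between MC38 and 4T1, of 6739 between LLC and 4T1 and of 3576 between LLC and MC38. In 100 draws with labels redrawn within each line, only the real labels gave as many, and the highest other counts were 4968, 6480 and 1965, all from draws that kept or mirrored a line's real grouping. A response in 1 line alone gives such counts, and mixed groups hold the treatment effect in their spread, so these draws do not test whether the responses differ, which rests on the edgeR test of the difference. Within a line the 6 libraries allow 10 splits, too few for a share under 0.05. The real splits gave 9285 genes in 4T1, 5047 in MC38 and 3702 in LLC, and the highest others 0, 1 and 0. The cholesterol list's medians were 1.99, 1.67 and 0.80 beside highest other values of 0.6212, 0.5331 and 0.3724. Each other split mixes control and sildenafil libraries, so its groups hold the treatment effect in their spread and keep part of it in their medians. These other values are therefore not a chance level. For genes called alike in all 3 lines, 1 of 100 combined splits gave as many as 896, the real split, and the highest other gave 0. A mixed line holds the treatment effect in its spread and calls almost no genes, so splits with a mixed line could share almost none, and this count does not test whether the overlap exceeds chance.

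Between MC38 and 4T1 the median difference in log2 fold change was -0.26 for NRF2 genes, -1.85 for interferon-response genes, -0.63 for MHC class I genes and 0.64 for ribosome biogenesis genes. Between LLC and 4T1 it was -1.11 for cholesterol synthesis, -0.54 for SREBP2-related regulation and uptake, -0.43 for fatty acid synthesis, -0.39 for NRF2 genes and 0.84 for ribosome biogenesis. Between LLC and MC38 it was -0.86 for cholesterol synthesis, -0.49 for SREBP2-related regulation, -0.35 for fatty acid synthesis, -0.43 for the integrated stress response, 0.34 for NF-kB genes, -0.55 for glycolysis and hypoxia and 1.01 for fibroblast markers. Differences of single genes between MC38 and 4T1 were 1.80 for Ciart, 1.79 for Chac1, 1.60 for Hbegf, 1.54 for Gadd45a, -3.35 for Ifit3, -3.11 for Ifi47, -2.89 for Dio2 and -2.85 for Gbp2. Between LLC and 4T1 they were 1.70 for Amotl2, 1.66 for Arf2, 1.66 for Ccdc137, 1.57 for Snhg15, -2.79 for Lpin1, -2.51 for Olfm1, -2.49 for mt-Rnr1 and -2.40 for Dbp. Between LLC and MC38 they were 2.86 for Abca1, 2.03 for Tgfbi, 2.01 for Ogn, 1.49 for Crybg1, -2.29 for Lpin1, -2.22 for Trib3, -2.05 for Tenm4 and -1.96 for Ddit3.

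The interferon response of 4T1 is the first pattern weighed. Leukocytes in the treated cultures are argued against by Ptprc, Tyrobp, Laptm5 and Cd52, whose highest mean in 4T1 sildenafil libraries was 0.103 CPM, although the markers Cd68 (10.2 to 38.7 CPM) and Cd74 (26.7 to 48.2 CPM) rose. Mixing with another of the lines is argued against by the list itself, since all 36 members averaged more in 4T1 sildenafil than in any group of the other lines, with a median ratio of 4.49. Interferon mRNA at harvest was near the floor, with 0.0948 CPM at most over 16 interferon genes, which leaves an earlier pulse open. An effect of sildenafil on 4T1 remains a hypothesis, and other inducers, such as nucleic acids or microbes in the culture, were not tested.

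RNAs without a poly(A) tail form the second pattern: over 72 of them (Rn7sk, Rn7s1, Rn7s2, Rmrp, Rpph1 and histone genes) MC38 controls exceeded 4T1 controls by a median log2 of 8.14 and LLC controls by 8.22. More cells in S phase would need a like shift in S-phase genes, which differed by 0.57 and 0.50. A different RNA selection or preparation between 4T1 and the other lines may account for the gap, although the labels give 1 kit. Since that kit is for polyA mRNA, the MC38 and LLC libraries are the ones that depart from the label. Preparation and line cannot be separated in differences between lines.

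Genes that move with Gm26917 between libraries of a group form the third pattern: 381 had r above 0.8 in both MC38 and LLC, where independent sets would share 122.7. A technical factor common to both sets of libraries may cause this, but a culture state common to both would give the same overlap. These genes were longer than others of like expression by a median ratio of 1.71, while their GC content was 3.65 percentage points higher, which lies between the bounds set for and against a GC effect. An effect of sildenafil on the same genes cannot be told apart from this factor. Their median in 4T1 of -0.0225 met the bound set beforehand against such an effect. It decides nothing, since members went both ways there (120 up, 139 down). These genes fell more often than they rose in MC38 (119 and 37) and LLC (78 and 9, or 285 and 10 without LLC control replicate 3). They were chosen by how they moved between these same MC38 and LLC libraries. Leaving 1 library out can shift such counts by the choice alone, so the 285 falls do not bear on an effect of sildenafil.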

How the results depend on the processing

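Protein-coding genes alone and the Gm26917 covariate were chosen after the results were seen. Under DESeq2, limma-voom, RLE factors, library totals, both filters and unrounded counts, the totals per line, between lines and over all 3 lines stayed within 1.5 times their reported values. So did the totals per line and over all 3 lines with all 18 libraries in 1 fit and with protein-coding genes alone, which was not run between lines, and those between lines from only the 12 libraries of 2 lines. Library totals gave more rises, 59% of the changes in 4T1, 59.7% in MC38 and 58.7% in LLC, beside 50.2%, 51.6% and 55.3%. A 2-fold threshold left 1033 genes in 4T1, 129 in MC38 and 273 in LLC, by its construction. The Gm26917 covariate left 937 genes in MC38 and 2251 in LLC, where it shares 0.856 and 0.462 of its variance with treatment. The cholesterol list kept its direction in each setting in which it was tested. It was not tested with DESeq2, limma-voom, unrounded counts or all 18 libraries in 1 fit. In LLC its camera call (median 0.80) was lost with an estimated correlation, adjusted p = 0.0621 in a range that fell to 3.93e-79 with no filter. With a list counted once in each line that called it, 50 other list calls were made. Of these, 39 were lost with an estimated correlation and 0 with fry. Of the lists that camera did not call, counted per line likewise, fry called 26 and left 11 uncalled. Since fry does not set a list against the other genes, many of which changed, it could hardly lose a call.

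Leaving out 1 library gave 8615 to 9564 genes in 4T1, 4026 to 4645 in MC38, 1841 to 5994 in LLC and 539 to 1213 shared by all 3. Between lines it gave 5014 to 6068 for MC38 and 4T1, 6237 to 7229 for LLC and 4T1 and 2899 to 4696 for LLC and MC38. The cholesterol medians ran from 1.97 to 2.02 in 4T1, 1.66 to 1.70 in MC38 and 0.77 to 0.86 in LLC.

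Among the named genes reported here, Srebf2 in LLC, not called, stood at -0.10 without control replicate 3 and -0.043 without sildenafil replicate 1, with up to 0.11 without control replicate 1, and was called at 0.30 with the Gm26917 covariate (adjusted p = 0.00362). Srebf1 in MC38, not called, stood at -0.0040 with DESeq2 and with RLE factors, -0.026 without control replicate 1, -0.015 without sildenafil replicate 1 and -0.018 without sildenafil replicate 2, in a range up to 0.039 without sildenafil replicate 3. With that covariate 28 named changes lost their call. The causes were not tested.

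With the replicate number as a block, 9090 genes changed in 4T1, 5867 in MC38 and 4078 in LLC, and 1028 were shared. Same-numbered libraries deviated together in some pairs only, with correlations from -0.0719 to 0.238, so the numbers are not treated as pairs, and not every library correlated best with its own number. Depth was not tested apart from spread: of simulated 1.3-fold changes 65.2% were recovered in 4T1, 60.6% in MC38 and 60.6% in LLC, and the biological coefficient of variation was 4.04%, 4.51% and 7.84%. The simulations changed far fewer genes than were called in the data.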

Other observations

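The tests of these lists were chosen after some of their genes had been seen to change, so each statement is a hypothesis. In 4T1 the host genes of small nucleolar RNAs fell, 12 of 12 measured, with a median of -0.84. Snhg1 fell by 1.28 ± 0.0326 and Gas5 by 0.94 ± 0.0375. In MC38 11 of 12 fell with a median of -0.21, and in LLC 2 rose and 1 fell. PPAR target genes, mostly of fatty acid oxidation, rose in 4T1 (12 of 16) and LLC (8 of 18, with 2 down), where Cpt1a rose by 1.04 ± 0.0706 and 1.45 ± 0.0519, and in MC38 7 of 17 rose and 4 fell. Circadian clock genes fell in 8 of 15 cases in LLC and rose in 1, while 8 of 16 rose and 6 fell in 4T1 and 6 of 15 rose and 3 fell in MC38. Dbp rose by 2.05 ± 0.0649 in 4T1 and fell by 0.34 ± 0.0647 in LLC.

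Camera was run on each list, adjusted over 9 tests, on the same libraries in which the genes had been seen to change. Its adjusted p does not allow for that choice, so it cannot decide whether a list changed together. For snoRNA host genes the adjusted p was 5.93e-10 in 4T1, 0.00084 in MC38 and 0.128 in LLC. For PPAR targets it was 0.000659 in 4T1, 0.821 in MC38 and 0.000237 in LLC. For clock genes it was 0.184, 0.23 and 0.000237. No list kept its call with an estimated correlation, where the lowest adjusted p was 0.068. Why the calls were lost was not tested, and a loss alone does not show that members moved together.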
